A study of Homo sapiens with 6 samples.

How the data were processed

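RNA was measured in 6 tumors grown from MDA-MB-231 cells, a human triple-negative breast cancer line, in the mammary fat pad of immunodeficient NOD/SCID mice. The cells were pools carrying a short hairpin RNA against the bacterial gene lacZ (shControl, 3 tumors) or against MEMO1 (shMemo, 3 tumors). Per the labels' protocols, mice of 6 to 8 weeks were injected, tumors were taken 4 weeks later and snap frozen, and RNA was amplified and biotin labelled as sense-strand whole-transcript target for Affymetrix arrays. One array of a 1-colour type was run per tumor.

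The authors deposited 1 normalized value per probe set and array. Per the submitters' processing notes, R 2.10.0 and affy were used. The background correction, the normalization, the annotation and the genome build are not given in the sources used here. The deposited values were taken as log2 expression from the values themselves, which ran from 1.09 to 13.6, with array medians of 4.67, 4.68, 4.69, 4.69, 4.68 and 4.71 for shControl 1 to 3 and shMemo 1 to 3 and closely similar quartiles. The log base and the centring are not stated by the authors, so fold changes printed here rest on a base of 2. No detection calls were used here, and the number of arrays limits the precision.

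The table held 32321 probe sets. The probe annotation paired 19158 of them with 1 gene symbol and 1388 with several, and 11775 were not named in it. Of the 19158, 19128 were matched by Entrez identifier to a gene table of the assembly GRCh38.p14, which was used for names only and changed 0 symbols. Probe sets with 1 symbol gave 18404 genes. For 637 genes with several probe sets, the probe set with the highest mean over the 6 arrays stood for the gene. No coordinates are printed because the build is not given. As a guide to background, the 360 olfactory receptor genes on the array had a median level of 2.56 and a 95th percentile of 3.83, and 69.3% of genes had a mean above that percentile.

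Each gene was tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with an empirical Bayes variance (no trend), 2-sided, without covariates. P-values were adjusted by the Benjamini-Hochberg method over the 18404 genes, and genes under an adjusted p of 0.05 were called. No filter on level was set. Means are given ± SD with 3 arrays per group, and log2 fold changes (shMemo minus shControl) with the standard error of the limma fit. Exact permutation tests of 3 against 3 arrays are 2-sided and cannot give a p below 0.1. No label says how the tumors of a group relate to each other beyond their number, so p-values measure only the spread between these tumors, which may be partly technical.

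Before the data were examined, 32 gene lists and 11 lists of markers of host cell types or RNA quality were fixed, with 942 different members, of which 838 were measured and the rest are not analysed here. The list of mitochondrially encoded RNAs had fewer than 5 measured members and was not tested, which left 42 lists. The result of 1 of these lists is not reported here. Lists were tested with limma's camera, which compares the members with all other genes, at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 42 lists. Camera with an estimated correlation, camera on ranks and fry, which asks whether the members move on balance in 1 direction, were run as alternatives. Members were also counted as past the threshold adjusted over the list alone. Because 54 genes are members of more than 1 list, the lists are not independent.

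The genes named in the text followed a rule fixed at the same time. It takes MEMO1, the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap, filling a direction that has too few up to 5 genes by lowest p-value, which are given as not past the test. It adds up to 4 members with the lowest p-values of each list described, and the extremes of the list of Memo partners. Genes named outside the rule are said to be so.

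The alternatives fixed before the data were examined were a block on the replicate number, limma with trend and robust variance, array weights, quantile normalization, centring on the median of named genes, filters at the 30th and the 50th percentile of level, the mean of a gene's probe sets, each probe set on its own, an unmoderated t statistic, a minimum of 1.5-fold, and leaving out each tumor in turn. A filter at the olfactory receptor 95th percentile and lists without their shared members were added after seeing the data.

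The gene and list tests were tested on simulated data with the real gene means and the fitted variance of the shMemo against shControl comparison. Of 18404 simulated genes, 100 were changed by 1 and 100 by 0.5 on the log2 scale. At the same threshold, 96% of the former and 58% of the latter were recovered, and 3 genes that were not changed were called. The simulated variances were drawn from the distribution that limma fitted, so they met the assumption of the test. The simulation called 158 genes against 19 in the real data, so its adjusted threshold was easier to reach. The recovered shares therefore do not carry over to the real genes. A list of 25 genes lowered by 0.25 was called and 0 of 40 unshifted lists were. The simulated genes were independent of each other, so the list test was not tried there on genes that vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.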

Results

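The expression data covered 6 xenograft tumors of MDA-MB-231 cells, 3 from shControl pools and 3 from shMemo pools, with 1 array each. MEMO1 encodes Memo, a protein known as a mediator of cell motility downstream of the receptor ERBB2. The comparison addressed how a lower level of MEMO1 in the injected cells relates to the transcripts of the tumors they form. The probes are human, so RNA of the mouse host could be seen only by cross-hybridisation. Across 18404 genes, arrays of the same group correlated at 0.995 to 0.997 and arrays of different groups at 0.993 to 0.996. The first principal component held 33.7% of the variance. On it, shMemo 1 and shMemo 2 lay at 16.4 and 11.8, shMemo 3 at -1.40, and the controls between -14.9 and -4.85.

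MEMO1 was lower in all 3 shMemo tumors. The probe set with the higher signal (8068410) read 6.54, 6.49 and 6.45 in the controls and 5.81, 5.90 and 5.88 in the shMemo tumors, a mean of 6.49 ± 0.0431 against 5.86 ± 0.0498 (SD, n = 3 each). The fall of 1.55-fold (log2 fold change -0.63, SE 0.0728) passed the test over all genes (limma adjusted p = 0.031). The other MEMO1 probe set (8051372) read 6.02 ± 0.112 against 5.29 ± 0.373, a difference of 1.66-fold in the same direction, with an adjusted p = 0.232 in limma when each probe set was tested on its own. An exact permutation test gave p = 0.1 for either probe set, the smallest that 3 against 3 arrays allow. The human gene table lists 6 MEMO1 pseudogenes, and whether the probes match these was not tested. Neither signal can therefore be assigned to MEMO1 alone, and the size of the fall is uncertain. The call rests on probe set 8068410 only. Without shControl 1, 2 or 3 the adjusted p in limma was 0.166, 0.134 and 0.0546, without shMemo 1 or 2 it was 0.112 and 0.139, and without shMemo 3 it was 0.0475, with log2 fold changes from -0.65 to -0.60.

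**Figure D1:**
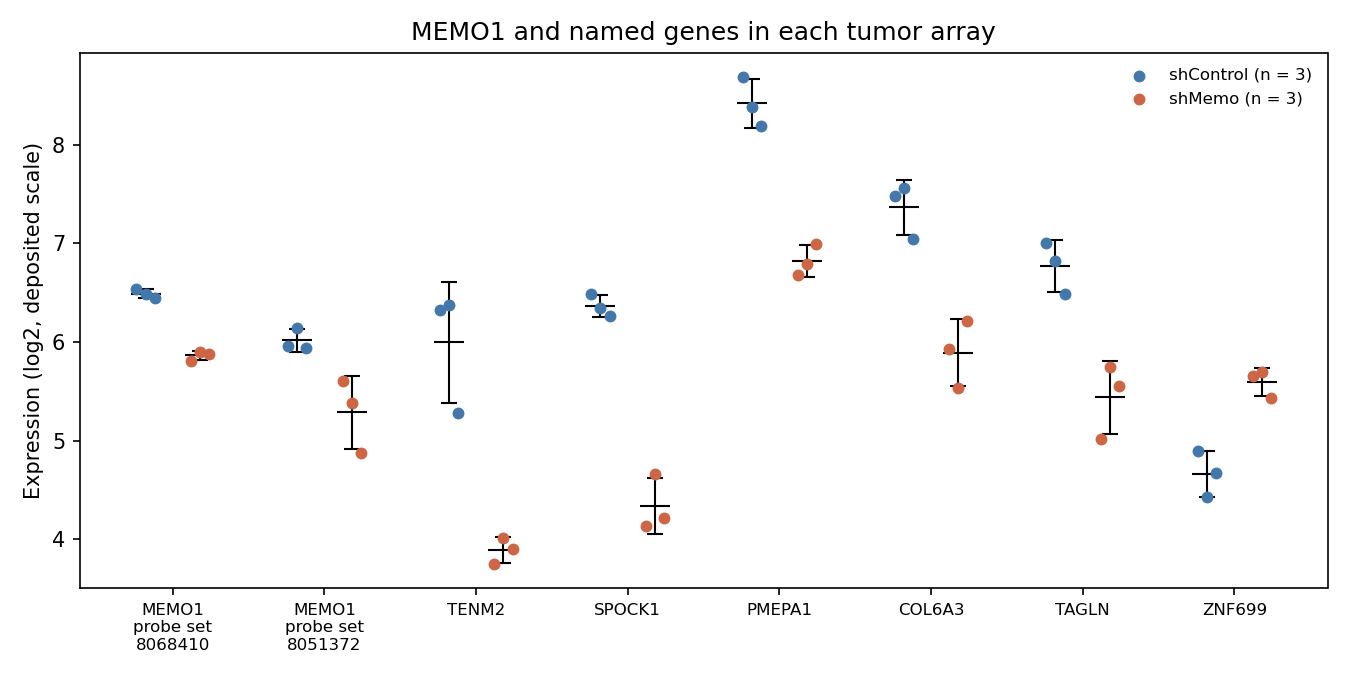
Expression (log2, deposited scale) of the 2 MEMO1 probe sets and 6 called genes in each array, with shControl in blue and shMemo in orange; bars are the mean ± SD of 3 arrays per group. For every item shown the 3 shMemo points lie on one side of the 3 control points, higher for ZNF699 and lower for the others, such as SPOCK1 with means of 6.37 and 4.34.

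Over all genes, 17 fell and 2 rose in the shMemo tumors. TENM2, a teneurin of the cell membrane, fell 4.30-fold, from 6.00 ± 0.617 to 3.89 ± 0.132, close to the olfactory receptor 95th percentile of 3.83. SPOCK1, the matrix proteoglycan testican-1, fell 4.08-fold, from 6.37 ± 0.112 to 4.34 ± 0.285, with the smallest adjusted p of all genes (0.00177 in limma). PMEPA1, a transcript induced by TGF-beta whose product restrains SMAD signalling, fell 3.02-fold, from 8.42 ± 0.248 to 6.82 ± 0.160 (limma adjusted p = 0.00562). COL6A3, a chain of collagen VI, fell 2.77-fold, and TAGLN, the actin-binding protein transgelin, fell 2.52-fold. The focal adhesion protein TNS1 fell 2.36-fold, the gap junction protein connexin 43 (GJA1) fell 2.29-fold and the unconventional myosin MYO1D fell 2.07-fold, to a mean of 3.75 that lies below that percentile, so its fold is uncertain. Smaller falls were those of the phospholipid phosphatase PLPP4 (1.99-fold), the secretory granule protein SCG5 (1.75-fold) and the Hedgehog-binding protein HHIP (1.70-fold). PCDHA13 fell 1.88-fold, but the protocadherin alpha genes share exons, so this signal cannot be assigned to 1 member with certainty.

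The other falls were COL5A1 (1.65-fold) and, outside the rule and named after their values were seen, LRP1 (1.65-fold), IGFBP7 (1.57-fold) and INSC (1.56-fold), besides MEMO1 itself. The shMemo mean of INSC, 3.58, lies below the olfactory receptor 95th percentile, so its fold is uncertain. The 2 rises were ZNF699, a zinc finger gene, from 4.66 ± 0.233 to 5.60 ± 0.139 (1.91-fold), and OR2M3, a member of the olfactory receptor family whose genes resemble each other, from 3.69 ± 0.204 to 4.49 ± 0.116 (1.74-fold); both had a limma adjusted p = 0.0496. The control mean of OR2M3 lies below the olfactory receptor 95th percentile, so its fold is uncertain too. The next genes in that direction did not pass in the reported fit. TLR4, a receptor for bacterial lipopolysaccharide, had a log2 fold change of 0.68 (SE 0.0993, limma adjusted p = 0.0572), FZD6, a Wnt receptor, of 0.48 (limma adjusted p = 0.103) and TMEM71 of 0.51 (limma adjusted p = 0.131). TLR4 passed in 6 of 11 alternatives that kept all arrays, 1 of them chosen after seeing the data, with a lowest adjusted p of 0.0187 with trend and robust variance, and without shMemo 3 (limma adjusted p = 0.0475). FZD6 passed with trend and robust variance (limma adjusted p = 0.0251) and at the 50th percentile filter (limma adjusted p = 0.0425), and TMEM71 with trend and robust variance (limma adjusted p = 0.0423). The groups did not overlap in 2774 genes, 15.1% against the 10% that chance gives on average. At an unadjusted p under 0.05 in limma there were 955 higher and 857 lower genes. On average 920 in both directions together would come by chance. Genes vary together, so a single split of the arrays can lie far from these averages. The 9 other splits of the arrays into 3 and 3, which mix the groups, gave from 473 to 1742 genes at that threshold.

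The counts rested on few tumors. Without shControl 1, 2 or 3, limma called 0, 1 and 1 higher and 2, 3 and 12 lower genes, and without shMemo 1, 2 or 3 it called 0, 0 and 16 higher and 2, 1 and 17 lower genes; where the higher count was 0, unadjusted p under 0.05 held for 888, 582 and 587 higher genes. SPOCK1 passed in all 6 of these fits and PMEPA1 in 5, missing without shMemo 2 (limma adjusted p = 0.0727), and the other called genes passed in 0 to 2. After quantile normalization 0 genes were higher and 15 lower (749 and 1069 at an unadjusted p under 0.05). Without moderation of the variance 0 genes passed in either direction (803 and 756 at an unadjusted p under 0.05), and on single probe sets 0 were higher and 8 lower (982 and 872).

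**Figure D2:**
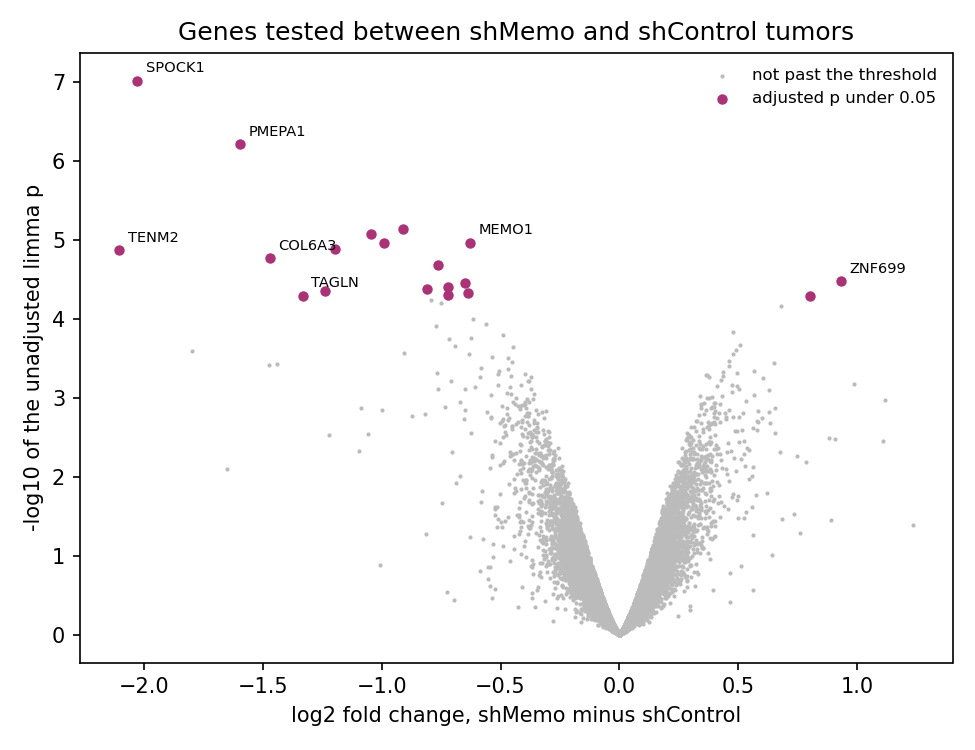
Log2 fold change (shMemo minus shControl, x axis) against -log10 of the unadjusted limma p (y axis) for the 18404 genes tested; each point is a gene, and the 19 called genes are in purple. 17 of the called genes lie on the left (lower in shMemo), led by TENM2, SPOCK1 and PMEPA1, and 2 on the right.

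Targets of TGF-beta were lower as a set in the shMemo tumors, with 21 of 24 measured members below the control mean and a median log2 fold change of -0.26. The camera adjusted p was 6.22e-12 at the preset correlation, and the call was lost with an estimated correlation (adjusted p = 0.134). Over all genes tested, PMEPA1 and TAGLN fell and 0 members rose. Adjusted over the list alone, 10 fell, 1 rose and 13 did not pass. Beside PMEPA1 and TAGLN, the falls over the list alone included COL1A1 (log2 fold change -0.51, SE 0.0968) and SMAD7 (-0.71, SE 0.139), an inhibitor of the pathway whose transcript TGF-beta induces. The member that rose over the list alone was LTBP1 (0.50, SE 0.176), which binds latent TGF-beta in the matrix. Its groups overlapped, and its log2 fold change was 0.31 without shMemo 1 and 0.71 without shMemo 3. The classical targets CCN1 and CCN2, singled out after their values were seen, had log2 fold changes of -0.24 and -0.080 and did not pass. CCN1 was at -0.11 without shMemo 1 and at -0.42 without shMemo 3, and CCN2 ran from -0.16 to 0.0079 over the arrays left out.

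SRF targets and genes of the actin cytoskeleton were lower as a set too, with 21 of 24 members below the control mean and a median of -0.14 (camera adjusted p = 1.87e-08, and adjusted p = 0.134 with an estimated correlation). TAGLN fell over all genes tested. Adjusted over the list alone 8 fell and 0 rose (0 higher at an unadjusted p under 0.05 in limma), among them the smooth muscle calponin CNN1 (log2 fold change -0.45, to a mean of 3.83 that lies at the olfactory receptor 95th percentile), the transcription factor SRF itself (-0.38) and the tropomyosin TPM1 (-0.65). Without shMemo 3, TPM1 passed over all genes (-0.79, limma adjusted p = 0.0475). In collagen and basement membrane genes, 23 of 28 lay below the control mean with a median of -0.12 (camera adjusted p = 2.01e-07, and adjusted p = 0.134 with an estimated correlation). COL6A3 and COL5A1 fell over all genes tested. Over the list alone 8 fell, COL1A2 (-0.49) and COL1A1 (-0.51) among them, and 1 rose, the laminin chain LAMB1 (0.27), named outside the rule after its value was seen. COL1A1 passed over all genes with trend and robust variance (limma adjusted p = 0.049), and COL1A2 at the 50th percentile filter (limma adjusted p = 0.0469).

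Mesenchymal genes had 21 of 23 members below the control mean and a median of -0.12 (camera adjusted p = 5.05e-07, and adjusted p = 0.134 with an estimated correlation). SPOCK1 fell over all genes tested, and over the list alone 5 fell and 0 rose (0 higher at an unadjusted p under 0.05 in limma), among them the transcription factors PRRX1 (log2 fold change -0.49) and ZEB2 (-0.37, and -0.18 with the mean of its probe sets) and the gelatinase MMP2 (-0.42). Markers of fibroblasts and pericytes, a host cell type list, moved the same way, with 17 of 18 below the control mean and a median of -0.19 (camera adjusted p = 2.01e-07, and adjusted p = 0.135 with an estimated correlation). Of these 18 markers 4 are also in a gene list and 9 lay above the olfactory receptor 95th percentile. None fell over all genes tested (0 in limma, 5 at an unadjusted p under 0.05). Over the list alone 4 fell: COL1A2, COL1A1, the smooth muscle actin ACTA2 (-0.40) and COL3A1 (-0.31). They are the same 4 markers that are also in a gene list, so their falls are not separate support. The mean of the list was -0.24, and it was -0.45 at the 50th percentile filter (camera adjusted p = 2.6e-07) and, in a test chosen after seeing the data, -0.16 without the members shared with other lists (camera adjusted p = 0.00284). In all 5 of these lists the mean of each shMemo array lay below that of each control array, with an exact permutation p = 0.1, the smallest possible. Skeletal muscle markers had a median of -0.26 too, but their arrays overlapped, with shControl 1 at -0.37 below every shMemo array. That call was lost with an estimated correlation (adjusted p = 0.713) and without shControl 2 (mean -0.075, camera adjusted p = 0.345), while without shControl 1 the mean was -0.53 (camera adjusted p = 5e-13).

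**Figure D3:**
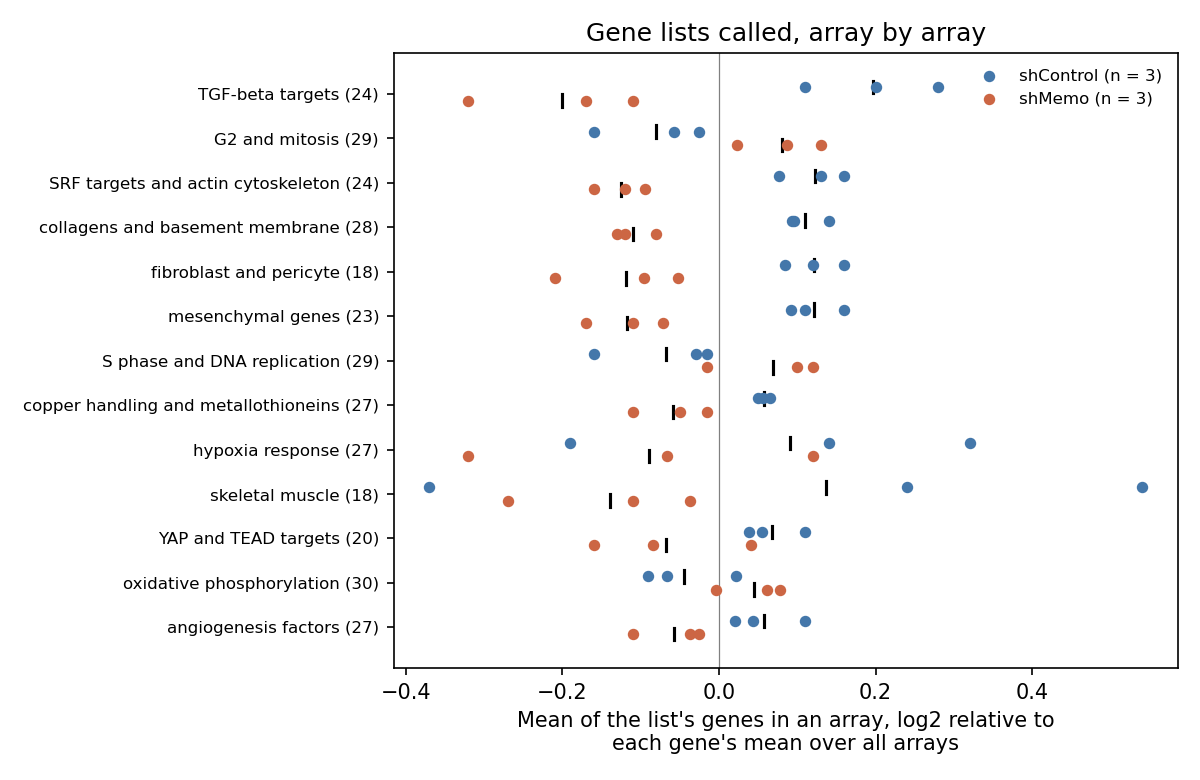
Mean of a list's genes in each array (x axis, log2 relative to each gene's mean over the 6 arrays) for the 13 lists called by camera, with the number of measured genes in brackets; points are arrays, shControl in blue and shMemo in orange, and black ticks are means of 3 arrays. The groups are apart in 8 lists, such as TGF-beta targets, and overlap in the other 5, such as skeletal muscle, where the controls run from -0.37 to 0.54.

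Cell cycle genes were higher as sets. Of the genes of G2 and mitosis, 26 of 29 lay above the control mean with a median log2 fold change of 0.14 (camera adjusted p = 1.87e-08, and adjusted p = 0.432 with an estimated correlation). Over all genes tested 0 members passed in limma (11 higher and 0 lower at an unadjusted p under 0.05). Adjusted over the list alone 2 rose, the spindle proteins NUSAP1 (0.40, SE 0.0867) and ASPM (0.34, SE 0.0752), while the kinetochore protein CENPF (0.25) and the motor KIF11 (0.31) did not pass. Of the genes of S phase and DNA replication, 26 of 29 lay above the control mean with a median of 0.12 (camera adjusted p = 2.08e-05, and adjusted p = 0.538 with an estimated correlation). In limma 0 members passed over all genes or over the list alone, with 6 higher and 0 lower at an unadjusted p under 0.05. The lowest p-values were those of cyclin E2 (CCNE2, 0.46), E2F8 (0.38), CDC45 (0.25) and PCNA (0.33, and 0.20 without shControl 3). The mean of the G2 and mitosis list separated the groups, while that of the S phase list did not, shMemo 3 and shControl 2 both lying at -0.015. Both lists were lowest in shControl 3, at -0.16, and without it the S phase list had a mean of 0.090 against 0.14 with it (camera adjusted p = 0.00584).

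Genes of oxidative phosphorylation had 23 of 30 members above the control mean and a median of 0.072 (camera adjusted p = 0.00424, and adjusted p = 0.622 with an estimated correlation). In limma 0 members passed over all genes or over the list alone, with 3 higher and 0 lower at an unadjusted p under 0.05. NDUFA5 (0.42), NDUFB5 (0.29) and NDUFB6 (0.26) of complex I and COX7B (0.31, and 0.17 without shMemo 1) of complex IV had the lowest p-values. The arrays of the groups overlapped, and the list was no longer called without shControl 2 (mean 0.067, camera adjusted p = 0.0894).

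Copper handling genes and metallothioneins were lower as a set, with 21 of 27 below the control mean and a median of -0.11 (camera adjusted p = 0.000453, and adjusted p = 0.135 with an estimated correlation). In limma 0 members passed over all genes or over the list alone, with 0 higher and 5 lower at an unadjusted p under 0.05. The metal-binding metallothioneins MT1X (log2 fold change -0.50), MT1B (-0.32) and MT1F (-0.33, and -0.21 without shControl 2) and the copper-dependent lysyl oxidase LOXL2 (-0.31) had the lowest p-values. Metallothionein genes resemble each other, so the 3 values are not certain to come from separate transcripts. The control arrays lay between 0.050 and 0.065 and the shMemo arrays between -0.11 and -0.015.

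Hypoxia response genes had 23 of 27 members below the control mean and a median of -0.16 (camera adjusted p = 0.00117, and adjusted p = 0.713 with an estimated correlation), but their arrays overlapped, with controls at 0.32, -0.19 and 0.14 and shMemo tumors at -0.32, -0.067 and 0.12. The call was lost without shControl 1 (mean -0.062, camera adjusted p = 0.362) and without shMemo 1 (mean -0.061, camera adjusted p = 0.241). Without shControl 2 and without shMemo 3 the mean was -0.32 and -0.28, against -0.18 with all arrays. In limma 0 members passed, with 0 higher and 4 lower at an unadjusted p under 0.05. The prolyl hydroxylase subunit P4HA2 (-0.63), ANGPTL4 (-0.53), AK4 (-0.28, and -0.16 with the mean of its probe sets) and BHLHE40 (-0.49) had the lowest p-values. Without shMemo 1, ANGPTL4 was at -0.33 and BHLHE40 at -0.27, and without shControl 1 ANGPTL4 was at -0.31. YAP and TEAD targets had 18 of 20 below the control mean and a median of -0.078 (camera adjusted p = 0.00387, and adjusted p = 0.538 with an estimated correlation), but the arrays of the groups overlapped, with shMemo 3 at 0.041 and shControl 3 at 0.038. Over all genes 0 passed in limma (0 higher and 3 lower at an unadjusted p under 0.05), and over the list alone TGFB2 (-0.82) and WWC1 (-0.48) fell, while CCND1 (-0.22) and GADD45B (-0.24, and -0.15 without shMemo 1) did not pass. The mean was -0.14, and -0.090 without shMemo 1 (camera adjusted p = 0.0426). The call was lost without shControl 1 (mean -0.11, camera adjusted p = 0.0568) and, in a test chosen after seeing the data, without the members shared with other lists (mean -0.094, camera adjusted p = 0.0781).

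Angiogenesis factors had 18 of 27 members below the control mean and a median of -0.077 (camera adjusted p = 0.0308, and adjusted p = 0.262 with an estimated correlation). Over all genes 0 passed in limma (1 higher and 5 lower at an unadjusted p under 0.05). Over the list alone the falls were those of THBS1 (-0.74), which codes for thrombospondin-1, an inhibitor of angiogenesis, and of the semaphorin SEMA3C (-0.50), while NRP2 (-0.49) did not pass. The call was lost without shControl 1 (mean -0.088, camera adjusted p = 0.106) and without shMemo 1 (mean -0.087, camera adjusted p = 0.0615), with camera on ranks (adjusted p = 0.0804) and, in a test chosen after seeing the data, without the members shared with other lists (mean -0.060, camera adjusted p = 0.304). At the 50th percentile filter the mean was -0.19 against -0.11 in the reported fit (camera adjusted p = 0.000455).

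The list of Memo partners and receptor signalling was not called as a set, with a median of -0.0054 and 9 of 21 members above the control mean (camera adjusted p = 0.5). In limma 0 members passed, with 1 higher and 3 lower at an unadjusted p under 0.05. Its extremes were FGFR1 (log2 fold change 0.24, SE 0.0849, limma adjusted p = 0.422) and IGF1R (-0.41, SE 0.117, limma adjusted p = 0.29), and GSK3B (-0.24) and IRS2 (-0.30) were also among the 4 members with the lowest p-values. Ligands of the epidermal growth factor family had a median of -0.017, a mean of 0.014 and a camera test pointing down (adjusted p = 0.958), so mean and test differ in sign. Over that list alone epiregulin (EREG, 0.60) rose, and the other 7 did not pass. MAPK feedback and immediate early genes had a median of 0.072 (camera adjusted p = 0.192), and were called higher without the members shared with other lists (mean 0.10, camera adjusted p = 0.0222), a test chosen after seeing the data. Genes of the NRF2 and oxidative stress response had a median of 0.0046 (camera adjusted p = 0.83). Over that list alone SLC7A11, the cystine transporter, rose (0.99, SE 0.196), with a limma adjusted p = 0.182 over all genes and of 0.006 without shMemo 3. PRDX3 (0.22) and GSR (0.22) did not pass, nor did AKR1C3, whose means of 3.63 and 3.32 lie below the olfactory receptor 95th percentile. NADPH oxidase complexes had a median of -0.015 (camera adjusted p = 0.613).

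Epithelial genes were not called as a set (median -0.010, mean -0.17, camera adjusted p = 0.0997), but 2 of 21 fell over the list alone. These were the desmosomal protein DSP, from 6.99 ± 0.264 to 5.55 ± 0.610, and keratin 7 (KRT7), from 9.48 ± 0.0874 to 8.01 ± 0.680, with limma adjusted p = 0.158 and 0.161 over all genes. Without shMemo 3, KRT7 passed over all genes (log2 fold change -1.76, limma adjusted p = 0.0475) and the list was called (mean -0.20, camera adjusted p = 0.0296). With all arrays, the list was also called without the members shared with other lists (mean -0.22, camera adjusted p = 0.0174), a test chosen after seeing the data. At the 50th percentile filter the mean was -0.35 and the list was not called (camera adjusted p = 0.0917). JUP (-0.26) did not pass, nor did CDH3, whose means of 3.25 and 3.04 lie below the olfactory receptor 95th percentile.

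Matrix proteases and their inhibitors had a median of -0.046 (camera adjusted p = 0.186) and were called lower at the 50th percentile filter (mean -0.12, camera adjusted p = 0.0209). Over the list alone ADAM19 (-0.45), MMP2 (-0.42) and the urokinase gene PLAU (-0.42) fell and the membrane metalloproteinase MMP16 (0.54) rose, of 37 measured. Among lung metastasis genes, defined in other work on MDA-MB-231 cells, the median was -0.088 (camera adjusted p = 0.228). Over the list alone EREG and the interleukin-13 receptor IL13RA2 (0.88) rose and MMP2 fell, while 18 of 21 did not pass. Bone metastasis genes had a median of -0.095 (camera adjusted p = 0.311). Integrins had a median of -0.062 (camera adjusted p = 0.219).

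In the other gene lists reported here the camera test did not pass and 0 members passed in limma over all genes or over the list alone. The median log2 fold change was 0.066 for p53 targets (adjusted p = 0.186, and 0.0146 with fry), -0.048 for NF-kappaB targets and inflammatory cytokines (adjusted p = 0.173), and -0.033 for the unfolded protein and amino acid stress response (adjusted p = 0.594). The NF-kappaB list was called lower at the 50th percentile filter (mean -0.12, camera adjusted p = 0.0146) and at the olfactory receptor filter (mean -0.091, camera adjusted p = 0.0352), which was chosen after seeing the data. At an unadjusted p under 0.05 the p53, NF-kappaB and unfolded protein lists had 1, 2 and 2 higher and 0, 5 and 2 lower members. Glycolysis (-0.029, adjusted p = 0.594), ribosomal proteins (0.013, adjusted p = 0.664) and antigen presentation (0.0098 with a mean of -0.017, adjusted p = 0.83) had 0 members in either direction at an unadjusted p under 0.05. Without shControl 2, glycolysis was called (mean -0.095, camera adjusted p = 0.0369). Cholesterol and fatty acid synthesis had a median of 0.035 (adjusted p = 0.634) and 1 higher and 0 lower members at an unadjusted p under 0.05. The interferon response had a median of -0.012, a mean of 0.023 and a test pointing up (adjusted p = 0.806), with 2 higher and 0 lower. Calcium, phosphate and vitamin D handling had a median of -0.017 (adjusted p = 0.68), with 1 higher and 3 lower. Stem cell and CD44 associated genes had a median of -0.039 (adjusted p = 0.379), with 0 higher and 2 lower.

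Of the host cell markers, those of skeletal muscle were called beside those of fibroblasts and pericytes. Muscle markers had 17 of 18 members below the control mean and a median of -0.26 (camera adjusted p = 0.00222, and adjusted p = 0.713 with an estimated correlation), and 9 of the 18 lay above the olfactory receptor 95th percentile. The spread lay in the controls, whose list means were -0.37, 0.54 and 0.24 against -0.11, -0.27 and -0.037 in the shMemo tumors, and without shControl 2 the call was lost. It was also lost at the 50th percentile filter (mean -0.28, camera adjusted p = 0.108). In limma 0 members passed, with 0 higher and 1 lower at an unadjusted p under 0.05. The muscle creatine kinase CKM had the lowest p-value, with a log2 fold change of -0.75, and of -0.43 without shControl 2. Next by p-value were MYH1 (means of 2.68 and 2.26), MYH4 (2.72 and 2.45) and TTN (3.47 and 3.10), which lie below the olfactory receptor 95th percentile in both groups, so their differences are uncertain.

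The remaining marker lists were not called. Medians were -0.0066 for macrophage and myeloid markers (camera adjusted p = 0.68), -0.018 for neutrophil (adjusted p = 0.639), -0.043 for lymphoid (adjusted p = 0.275) and -0.040 for endothelial markers (adjusted p = 0.403). Adipocyte markers had a median of -0.035, a mean of 0.077 and a test pointing up (adjusted p = 0.83). Over that list alone the fatty acid binding protein FABP4 rose, from 2.88 to 4.00, from below to just above the olfactory receptor 95th percentile, while the other 15 did not pass. Erythroid markers had a median of -0.053 (adjusted p = 0.482), and the delta globin HBD, from 3.95 to 3.32, fell over the list alone, to below the olfactory receptor 95th percentile. The other 6 did not pass. Markers of normal mammary epithelium had a median of 0.026, a mean of -0.041 and a test pointing down (adjusted p = 0.83). The actin ACTG2 fell over that list alone (-0.65), and the other 17 did not pass. Replication histones, read as a sign of RNA quality, had a median of 0.050 (adjusted p = 0.445) and were called without shControl 1 (mean 0.078, camera adjusted p = 0.0405).

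In all, camera called 13 of 42 lists at the preset correlation, 3 higher and 10 lower. With an estimated correlation it called 0, so no list call held there. In that setting 7 lists had an unadjusted camera p under 0.05, and the smallest adjusted p was 0.134. The estimated correlation was 0.724 for hypoxia genes and 0.281 for G2 and mitosis. It was 0.0136 for copper genes, near the preset, and -0.021 for angiogenesis factors, below it. For copper genes and angiogenesis factors a higher correlation therefore cannot be the whole reason. What else lost these calls was not tested. Fry called 6 lists: TGF-beta targets, SRF targets and actin cytoskeleton, collagens and basement membrane, mesenchymal genes, fibroblasts and pericytes, and p53 targets.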

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

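The filter at the olfactory receptor 95th percentile and the lists without shared members were chosen after seeing the data. Every called gene and list named here kept its direction under all alternatives run. This was largely fixed in advance, so it is weak support. The groups of the called genes do not overlap, nor do the arrays of 8 called lists. Leaving out 1 tumor therefore cannot reverse these. Several alternatives, such as the block, the trend and the unmoderated t statistic, also reuse the same fold changes. The estimated correlation, ranks and fry reuse the same list means. Genes higher, 2 in the reported fit, numbered 6 with trend and robust variance and 0 with quantile normalization, on single probe sets and without moderation. Genes lower, 17, numbered 8 on single probe sets and 0 without moderation. The other alternatives that kept all arrays gave counts within 1.5 times of these, apart from the replicate block. At the 50th percentile filter the 2 higher genes were not the 2 reported ones, which lay below the filter, but TLR4 and FZD6, and of 15 lower genes 12 were among the 17. The replicate block left 0 higher and 1 lower gene and MEMO1 at -0.63 (adjusted p = 0.131), with 13 lists called. Deviations of arrays with the same number correlated at 0.039, 0.013 and 0.20, and only shControl 3 and shMemo 3 correlated best with their own number. On the second principal component (22% of the variance) these 2 arrays lay at -9.33 and -11.3. There shControl 1 and 2 lay at 9.07 and 12.8, and shMemo 1 and 2 at -1.15 and -0.097. With 3 arrays per group these values cannot decide whether the numbers pair the tumors. MEMO1 missed the threshold with the mean of its probe sets (-0.68, adjusted p = 0.0518) and without moderation (-0.63, adjusted p = 0.242), and its adjusted p ran from 0.0143 to 0.242 over the alternatives that kept all arrays. Leaving out 1 tumor gave 0 to 16 genes higher, 1 to 17 lower, MEMO1 at -0.65 to -0.60 and 11 to 14 lists called. Of 13 lists called, 0 were called with an estimated correlation and 6 with fry, 5 of them among the 13. The cause was not tested for these changes.

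Direction reversed only in lists that were not called and in CCN2, also not called, which ran from -0.16 to 0.0079 over the arrays left out. With quantile normalization NRF2 genes had a mean of -0.0057 and ribosomal proteins of -0.0080. Lung metastasis genes had 0.015 at the 30th percentile and at the olfactory receptor filter, 0.066 at the 50th percentile and 0.013 without shared members. Macrophage markers had 0.010 at the 30th percentile and 0.0021 at the olfactory receptor filter. At the 50th percentile antigen presentation had 0.033, calcium handling 0.0036 and endothelial markers 0.032, and epidermal growth factor ligands had -0.052 without shared members. Over the arrays left out, means ran from -0.024 to 0.040 for these ligands, -0.095 to 0.038 for glycolysis, -0.043 to 0.029 for the unfolded protein response, -0.070 to 0.016 for lung metastasis genes, -0.025 to 0.047 for ribosomal proteins, -0.0052 to 0.066 for cholesterol synthesis, -0.046 to 0.022 for antigen presentation, -0.048 to 0.017 for macrophage markers and -0.014 to 0.043 for NRF2 genes. The cause was not tested. Low signal limits the marker lists, of which neutrophil markers had 1 of 10 members above the olfactory receptor 95th percentile.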

Other observations

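The comparison of other splits by number of genes, the test on fibroblast markers and the test without shControl 3 were chosen only after the result was seen. The TGF-beta targets were followed up with a second list of 19 genes induced by TGF-beta that shares no member with the first, fixed before the values of the second were examined, though 5 of its members are in other fixed lists whose results had been seen. Of 18 measured, 14 lay below the control mean, with a median log2 fold change of -0.16. The kinase gene SPHK1 (-0.48, SE 0.115, limma adjusted p = 0.219 over all genes) fell adjusted over the list alone. TUFT1 (-0.50) and CHST11 (-0.40) followed by p-value without passing, as did WNT5A, whose shMemo mean of 3.64 lies below the olfactory receptor 95th percentile.

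The lower TGF-beta, actin, collagen and mesenchymal genes in the shMemo tumors, 97 genes together, differed by a mean of -0.26 (SE 0.0298) on the log2 scale. They come from lists picked because these same data called them lower, so this difference is not independent support. Among the other splits of the arrays the smallest camera p of these genes was 2.71e-05, against 5.91e-21 for the real one. With the mean of the muscle markers as a covariate the mean difference was -0.27 (SE 0.0366), which argues against less host muscle RNA as the whole cause. Less host fibroblast RNA stays open. Fibroblast markers in no other list had a median of -0.125, but only 4 of these 13 lay above the olfactory receptor 95th percentile. Probes near background can understate a fall. In a test chosen after seeing the data, these 13 were still called lower as a set (mean -0.16, camera adjusted p = 0.00284 at the preset correlation). Lower TGF-beta signalling in the tumor cells may account for the pattern as a hypothesis, and the second list gave a camera p of 0.00011 at the preset correlation, but p = 0.121 with an estimated correlation, and among the 9 other splits of the arrays 4 gave a p under 0.05, the smallest 0.000102. The second list therefore does not decide, and a lower level of MEMO1 itself is not tested apart from the pools that carry the hairpins.

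The higher cell cycle genes, 58 of G2, mitosis and S phase, had a median log2 fold change of 0.14, and 52 lay above the control mean. A trend of fold change with brightness is argued against, as 10000 random lists matched on mean level had a median of 0.0269 and the highest of them reached 0.091. Without the array shControl 3 the mean difference was 0.106 (SE 0.0457) against 0.15 (SE 0.0553) with it, so it shrank but kept its direction. On so few arrays these standard errors cannot decide whether shControl 3 alone accounts for the pattern. What else distinguishes the shMemo tumors was not tested for this pattern. Among the other splits the smallest camera p of these genes was 7.15e-09 against 7.43e-12 for the real one. The cell cycle genes come from lists that these same data called higher, which favours the real split. Neither this comparison nor the one with random lists is independent support for the rise.

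For the count of genes, the real split of the 6 arrays called 19, and 1 of the 10 possible splits, the real one, called as many, with 0 as the highest of the others (at most 1742 at an unadjusted p under 0.05 in limma, against 1812). For the count of lists, the real split called 13 and 1 of 10 splits called as many, with 11 as the highest of the others. With 10 splits no share under 0.05 can be reached. Camera at the preset correlation called 1 or more lists in each of the other splits.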
